A study of Mus musculus with 20 samples.

How the data were processed

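CUT&Tag was done with a Vazyme Hyperactive Universal kit on C2C12 mouse myoblasts of wild-type genotype, treated for 6 h with DMSO or 100 nM thapsigargin, per the labels' protocols. The series lists 20 samples, 5 targets in 2 treatments with 2 replicates each. Groups were taken from the sample titles and treatment labels. Nothing in the labels says whether the replicates came from separate cultures.

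The deposited files hold 1 ATF4 peak list per treatment, as chromosome, start and end with no header and no height, score, summit, p or q. Trim Galore 0.6.10, Bowtie2 and MACS2 2.2.7.1 and the build mm10 are named per the submitters' processing notes, without roles, parameters or thresholds. A control library, the peak threshold and whether and how replicates were combined into 1 list are not given in the sources used here. Read depth per sample is therefore unknown, and a longer list may reflect deeper reads, a looser threshold or more binding. No peaks of 1 list overlapped each other, and all lay on chromosomes 1 to 19 and X. The other 8 groups were not used here.

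Gene positions came from a RefSeq gene table of the mouse assembly GRCm38.p6, to which mm10 corresponds, with 21631 protein-coding genes on chromosomes 1 to 19 and X. The table gives the start and end of each gene without strand or exons. The tests had been planned around transcription start sites, a per-peak score and genome sequence. In their place the distance from the peak centre to the nearer end of a gene was used, so a peak at a gene's 3' end counts like one at its start, exons and introns were not told apart, and peaks were ranked by width. The planned search for 8 motifs was not run, as no genome sequence was used here. A stricter q threshold was not run either, and the wider part of each list was used in its place. Printed coordinates count from 1.

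Before the data were examined, the tests, 13 gene lists and the genes to be named were fixed. The rule named the 10 highest-ranked shared peaks, the 10 highest-ranked peaks of the thapsigargin list alone and up to 5 of the DMSO list alone, each with a gene whose end lay within 10 kb. It also named up to 6 members per list in order of the width of their thapsigargin peak, and 10 genes in any case, which were Atf4, Ddit3, Cebpb, Cebpg, Asns, Trib3, Chac1, Atf3, Sesn2 and Psat1. Where no gene end lay within 10 kb, the gene around the peak was given. Some of the genes that the rule names are not reported here. The lists cover stress response regulators, amino acid synthesis, amino acid transport, cytosolic and mitochondrial aminoacyl-tRNA synthetases, translation factors, ER chaperones, autophagy, oxidative stress, mitochondrial stress, circadian and bZIP factors, skeletal muscle identity and markers of other cell types. Some lists were drawn from textbook ATF4 targets, so their binding is no unbiased survey.

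Peaks counted as overlapping when they shared at least 1 bp. The background was 100 shuffles of the DMSO peaks within the annotated span of their chromosomes, and for location 20 shuffles of each list. Rank percentiles were compared with a two-sided permutation test of medians (100000 resamples), shares with Wilson intervals at the 95% level, and location and gene overlap with two-sided Fisher's exact tests. A gene counted as bound when a peak centre lay within 1 kb of either of its ends. Lists were tested with one-sided Fisher's exact tests for more peaks than in all other protein-coding genes, with Benjamini-Hochberg adjustment over 26 tests and a threshold of 0.05. Odds ratios carry a correction of 0.5 per cell. The test of lists already bound in DMSO is a two-sided Fisher's exact test with the thapsigargin-bound genes as background. It was added after the list counts had been seen and is adjusted over 11 lists.

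Alternatives were other overlap rules (50% of a peak's length, centres within 100 bp, within 1 kb), merging of peaks within 500 bp, as many thapsigargin as DMSO peaks, windows of 500 bp, 3 kb and 5 kb, the nearest gene within 50 kb, all gene types, and genes with a peak within 50 kb as background. The upper part of each list by width (402 DMSO and 4310 thapsigargin peaks) and the distance to the peak edge were added after the data had been seen.

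Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 11. The overlap and list tests were tested on simulated data: 400 of 400 copied peaks and 4 of 400 shuffled ones were found as overlapping. Over 21631 genes, 10 of 10 lists of 20 genes with 12 planted members were called at an adjusted p of 0.05, against 0 of 200 random lists, of which 7 had an unadjusted p under 0.05. Lists with fewer planted members were not simulated.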

Results

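ATF4, the bZIP transcription factor that drives gene expression in the integrated stress response, was mapped in C2C12 cells, a line of mouse myoblasts. The cells were treated for 6 h with DMSO, the solvent, or with 100 nM thapsigargin, an inhibitor of the calcium pump of the endoplasmic reticulum (ER) that causes ER stress. The assay was CUT&Tag, in which an antibody brings a transposase to the protein of interest and the DNA next to it is tagged and sequenced. The series held 20 samples in 10 groups of 2 replicates, covering ATF4, CHOP, CEBPβ, CEBPγ and acetylated histone H3 (H3K27Ac) in both treatments. The results below rest on the authors' ATF4 peak lists, 1 for DMSO and 1 for thapsigargin, and 8 groups were not used here. Each list was taken to stand for a condition as a whole, so there was no replicate error, and the read depth behind the lists is unknown. Intervals of shares are 95% Wilson intervals and cover counting error only. Intervals of other values are 95% intervals of other kinds, and none covers replicate error. Tests over peaks or genes describe these lists, since peaks and genes are not replicates.

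The first comparison asked which sites ATF4 occupied without added stress, and whether these were the sites it occupied in thapsigargin. Among the 10 genes that were to be named whatever their peaks, 8 carried an ATF4 peak centred within 1 kb of a gene end in both conditions. With peak centres within 500 bp 5 did, and Ddit3, Cebpb and Psat1 dropped out, though their peaks in both conditions covered a gene end. The 8 were Ddit3, which encodes the stress factor CHOP, Atf3, Cebpb and Cebpg, which encode bZIP partners, the pseudokinase gene Trib3, the glutathione-degrading enzyme gene Chac1, and Asns and Psat1, which encode enzymes of asparagine and serine synthesis. Sesn2, a stress-induced regulator of mTORC1, had a peak at its end only in thapsigargin, centred 99 bp from the gene end, while the nearest DMSO peak lay 3588 bp away. Atf4 itself had no peak nearby in either condition, and the nearest ones were 35.4 kb away.

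The positions are those of mm10. At Ddit3 (chromosome 10, 127290793 to 127296291) the DMSO peak spanned 127289294 to 127291178 and the thapsigargin peak 127289252 to 127291671, over the end of the gene and the adjoining end of Mbd6. At Asns (chromosome 6, 7675165 to 7693209) the peaks spanned 7692561 to 7693589 in DMSO and 7692609 to 7693798 in thapsigargin, across the gene end. The Trib3 peak in thapsigargin (chromosome 2, 152343245 to 152344859) was centred 8.5 bp from the gene end and was 1615 bp wide, against 954 bp in DMSO. The Chac1 peak (chromosome 2, 119350158 to 119351644) was 1487 bp wide in thapsigargin and 1364 bp in DMSO. The Atf3 peak (chromosome 1, 191182468 to 191183863) was 1396 bp wide in thapsigargin and 1177 bp in DMSO. At Psat1 (chromosome 19, 15905123 to 15925059) the width was 2105 bp in thapsigargin and 936 bp in DMSO. The Cebpb peak (chromosome 2, 167689079 to 167690433) lay over the gene itself, with 1355 bp in thapsigargin and 767 bp in DMSO, and the Cebpg peak (chromosome 7, 35055775 to 35056752) was 978 bp wide in thapsigargin and 877 bp in DMSO.

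**Figure D1:**
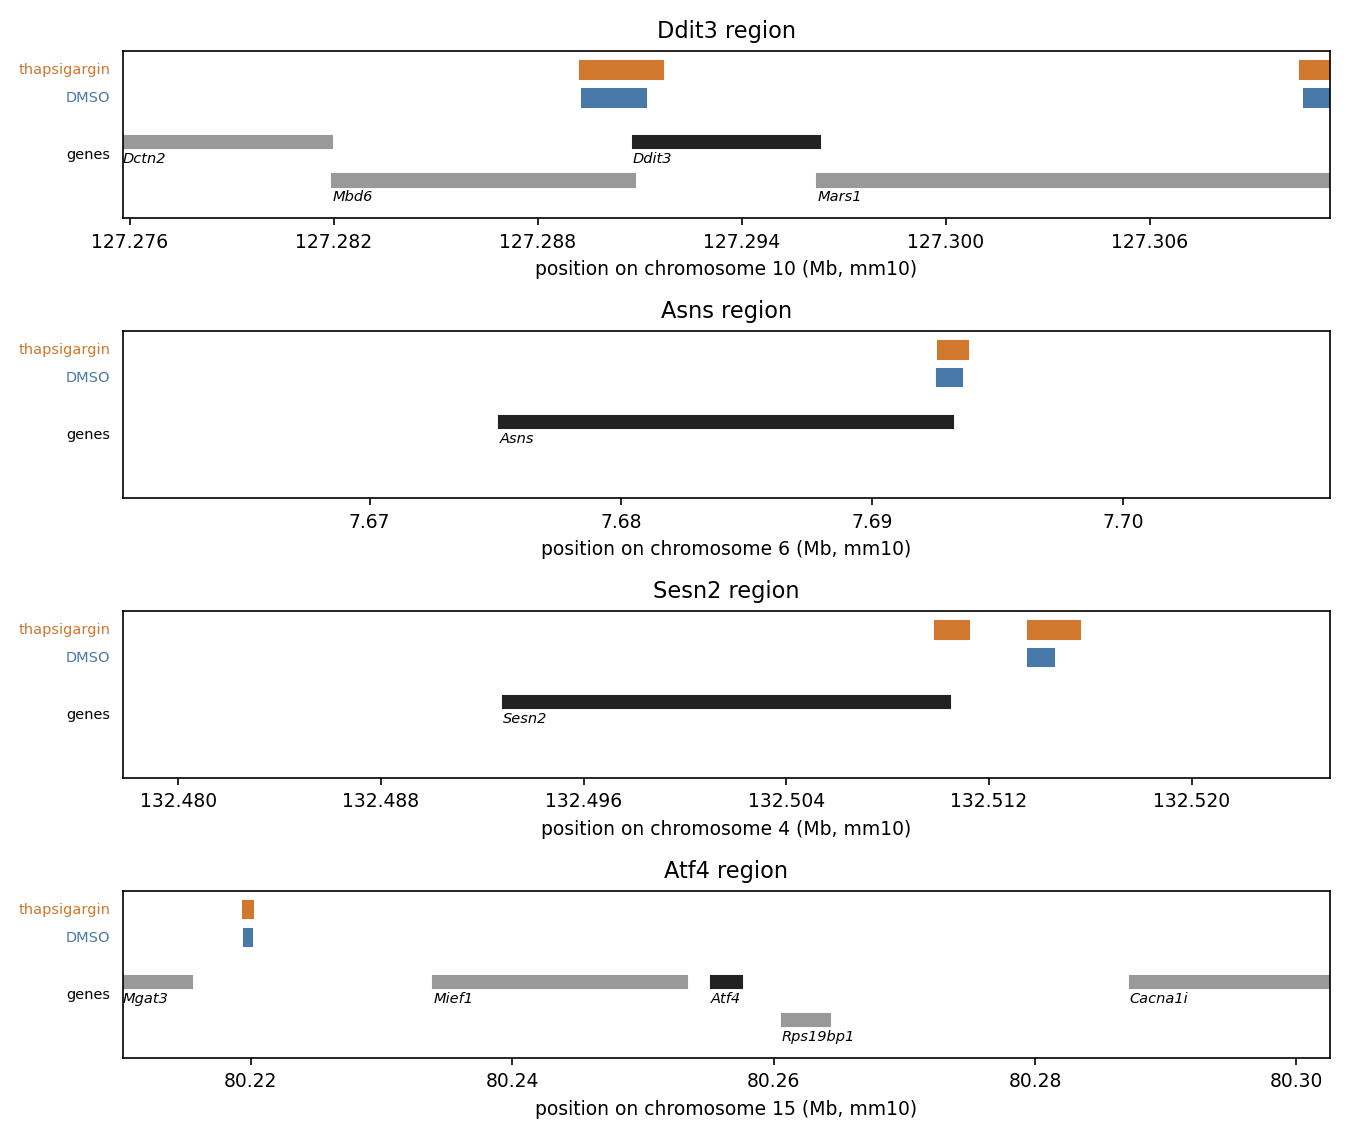
Maps of the Ddit3, Asns, Sesn2 and Atf4 regions, with the position on the chromosome (Mb, mm10) on the horizontal axis. Orange bars are ATF4 peaks in thapsigargin, blue bars ATF4 peaks in DMSO, and black and grey bars protein-coding genes; Sesn2 has a peak at its end only in thapsigargin, and Atf4 has none within 35.4 kb.

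Across the genome, ATF4 had 803 peaks in DMSO and 8619 in thapsigargin, 10.7 times as many. The peaks covered 0.714 Mb in DMSO and 9.37 Mb in thapsigargin, 13.1 times as much, and their median width was 856 bp and 1037 bp. Nearly every DMSO peak was found again in thapsigargin: 799 of 803 (99.5%, interval 98.7% to 99.8%) overlapped a thapsigargin peak by at least 1 bp. In 100 shuffles of the DMSO peaks within their chromosomes, 6.08 peaks overlapped on average and 13 at most. Conversely, 797 of 8619 thapsigargin peaks (9.25%, interval 8.65% to 9.88%) overlapped a DMSO peak, so most sites in the thapsigargin list had no DMSO peak. The number of peaks called depends on read depth and on the authors' threshold as well as on binding, and the lists do not separate these. With a match of peak centres within 100 bp in place of any overlap, the share of DMSO peaks found again was 51.1%.

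The 4 DMSO peaks without a thapsigargin overlap lay near Btaf1 (1.2 kb from the gene end), Ccdc136 (1.57 kb), Atf5 (2.23 kb) and, on chromosome 10 from 37483782 to 37484918, at no gene end within 10 kb. The peak near Atf5, which encodes a bZIP factor of the stress response, spanned 44818421 to 44819353 on chromosome 7, inside Nup62. Its nearest thapsigargin peak was 29.3 kb away, whereas the one near Ccdc136 had a thapsigargin peak 1.6 kb away.

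At genes, 278 of 21631 protein-coding genes (1.29%) had a DMSO peak centred within 1 kb of a gene end and 3267 (15.1%) had a thapsigargin peak there. Both lists marked 274 of these genes, where independent lists would share 42.0 (odds ratio 374, Fisher's exact test, two-sided, p = 6.74e-222). The odds ratio was 62.3 with a window of 500 bp and 239 with 5 kb.

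The next comparison asked whether sites bound in both conditions differed from those bound in thapsigargin alone. The lists give no height or score, so peaks were ranked by width, which is not a measure of occupancy. Thapsigargin peaks that overlapped a DMSO peak had a median width of 1377 bp, and the remaining 7822 had 1005 bp. Their median rank percentiles within the thapsigargin list were 78.8 and 46.6, a difference of 32.2 points (permutation test, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). The share overlapped by a DMSO peak was 0.58% among the 862 narrowest peaks of the thapsigargin list and 25.6% (interval 22.8% to 28.7%) among the 862 widest. Wide peaks overlap others more easily, but shuffled DMSO peaks hit thapsigargin peaks with a median width of 1139 bp. Of the 803 widest thapsigargin peaks, 25.3% overlapped a DMSO peak.

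**Figure D2:**
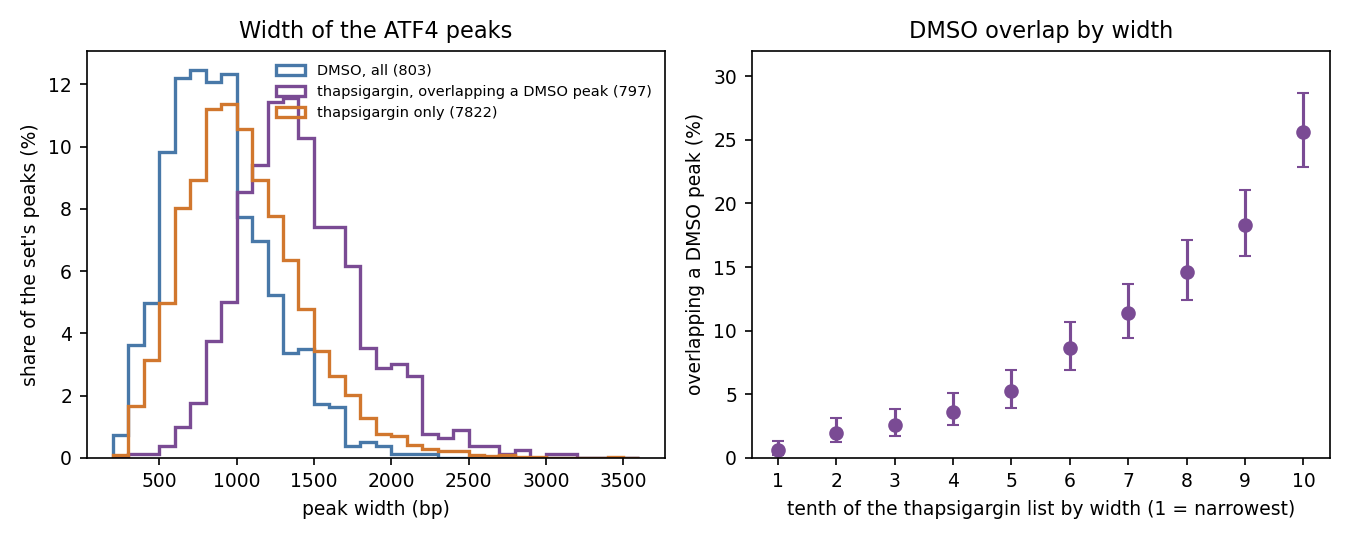
Left, the share of peaks (%) by peak width (bp) for the 803 DMSO peaks, the 797 thapsigargin peaks that overlap a DMSO peak and the 7822 that do not. Right, the share of thapsigargin peaks that overlap a DMSO peak (%, points with 95% Wilson intervals) in 10 groups of the thapsigargin list by width, from 0.58% in the narrowest group to 25.6% in the widest.

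The widest of the shared peaks included one at Hspa5, the gene of the ER chaperone BiP (chromosome 2, 34769492 to 34772310, 2819 bp wide in thapsigargin, centred 1.19 kb from the gene end). Others were near Rusc2 and near Cttnbp2nl, and inside Myh9, Fam13b, Larp1 and Runx2 over 10 kb from the gene ends. The widest peaks of the thapsigargin list without a DMSO overlap were inside Smim3 (chromosome 18, 60499841 to 60503339, 3499 bp) and Loxl2 (chromosome 14, 69690633 to 69694117, 3485 bp). Further ones lay at Ern1, which encodes the ER stress sensor IRE1 (2720 bp, centred 0.99 kb from the gene end), at Jun (2717 bp, 64.5 bp from the gene end) and at Snai2, a transcription factor gene of mesenchymal cells (0.746 kb). Peaks of this class were also found near Tslp, Zswim4 and Dmbx1 and inside Bach2.

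At the shared sites the DMSO peak was usually a narrower peak inside the thapsigargin peak. In 779 of 799 pairs the DMSO peak was the narrower one (exact binomial test, two-sided, p = 2.24e-201), and in 706 pairs (88.4%) it lay wholly inside. The median width was 856 bp in DMSO and 1378 bp in thapsigargin, with a median ratio of 1.56 and centres 97 bp apart. Peak width also depends on read depth.

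The place of the peaks relative to genes was compared next. In DMSO 29.3% of the peaks (235 of 803, interval 26.2% to 32.5%) and in thapsigargin 31.8% (2739 of 8619, interval 30.8% to 32.8%) were centred within 1 kb of an end of a protein-coding gene. Shuffled peaks gave 3.15% and 3.11%. A further 35.4% of the DMSO peaks and 34.0% of the thapsigargin peaks lay elsewhere inside a gene, and 35.4% and 34.2% outside genes. Of the peaks bound in both conditions 29.4% (234 of 797) were at a gene end, against 2505 of 7822 of those in thapsigargin alone, an odds ratio of 0.883 that did not pass the test (Fisher's exact test, two-sided, p = 0.129). In the same exact test a window of 500 bp gave an odds ratio of 0.734 (p = 0.000464) and all gene types gave 0.842 (p = 0.028), so that the call depended on the setting. In the upper part of each list by width the same exact test gave 1.03 (p = 0.818). There only overlap with the upper part of the DMSO list counted as shared. Thapsigargin peaks over narrower DMSO peaks thus counted as thapsigargin alone, so this value cannot be set directly against the others.

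The fourth comparison asked at which groups of genes ATF4 was found in stressed cells. In thapsigargin, 10 of 13 gene lists had peaks at their gene ends more often than other protein-coding genes (15.1%), by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 26 tests. Amino acid synthesis and one-carbon metabolism had 15 of 21 members with a peak (odds ratio 13.5, adjusted exact p = 5.36e-08), led in width by Aldh18a1 in proline synthesis (2272 bp), Psat1, Shmt2, Bcat1, Phgdh and Gpt2. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, had 13 of 20 (odds ratio 10.2, adjusted exact p = 2.1e-06), among them Mars1 (2069 bp), Vars (2006 bp), Gars, Iars, Tars and Sars. The amino acid transporters had 8 of 16 (adjusted exact p = 0.00239), with Slc6a9, Slc38a2, Slc7a5, Slc7a1, Slc1a4 and Slc38a7, a call lost with a window of 500 bp (5 of 16, adjusted exact p = 0.0656). The transcription factors and regulators of the integrated stress response had 16 of 29 (odds ratio 6.9, adjusted exact p = 2.17e-06), with Ddit3 (2420 bp), Ddit4, Herpud1, Stc2, Nupr1 and Jdp2 the widest.

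Genes of protein folding and turnover were marked as well. Of the ER chaperones and ER-associated degradation factors, 17 of 26 had a peak (odds ratio 10.4, adjusted exact p = 5.36e-08), including the stress sensors Ern1 (2720 bp) and Atf6 (2450 bp) and the chaperones or co-chaperones Calr, Dnajb11, Hsp90b1 and Dnajb9. The autophagy list had 11 of 16 (odds ratio 11.8, adjusted exact p = 4.98e-06), with Becn1, Wipi2, Nbr1, Gabarapl2, Atg3 and Atg16l1. The circadian and bZIP factors had 15 of 25 (odds ratio 8.33, adjusted exact p = 1.47e-06), with Jun, Per2, Bhlhe40, Junb, Nfe2l2 and Atf7. The translation factors had 12 of 21 (adjusted exact p = 2.52e-05), with Eif4a1, Eif1, Eef1a1, Eif2s2, Eif2b4 and Eif2s3x. The oxidative stress list had 6 of 12 (adjusted exact p = 0.00779), namely Gclm, Txn1, Hmox1, Srxn1, Prdx1 and Nqo1, and lost the call against genes with a peak within 50 kb (adjusted exact p = 0.078). The mitochondrial stress list had 5 of 8 (adjusted exact p = 0.00546), namely Lonp1, Hspd1, Hspe1, Dnaja3 and Hspa9, where the neighbours Hspd1 and Hspe1 share 1 peak. With the nearest gene within 50 kb it had 4 of 8 and lost the call (adjusted exact p = 0.142).

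The remaining 3 lists did not pass. The mitochondrial aminoacyl-tRNA synthetases had 3 of 17 (17.6%, adjusted exact p = 0.601). None of 24 genes of skeletal muscle identity and differentiation, such as Myod1, Myog and Des, and none of 22 markers of other cell types, such as Alb and Snap25, had a peak at a gene end in either condition (adjusted exact p = 1 for both lists). The counts of 0 allow shares of up to 13.8% and 14.9% by the Wilson interval, against 15.1% of other genes in thapsigargin. With wider reach this lack was smaller: 2 of 24 muscle genes (8.33%) had a thapsigargin peak within 5 kb, against 21.1% of other genes, and 5 of 24 (20.8%) were the nearest gene to a peak within 50 kb, against 24.2% of other genes.

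**Figure D3:**
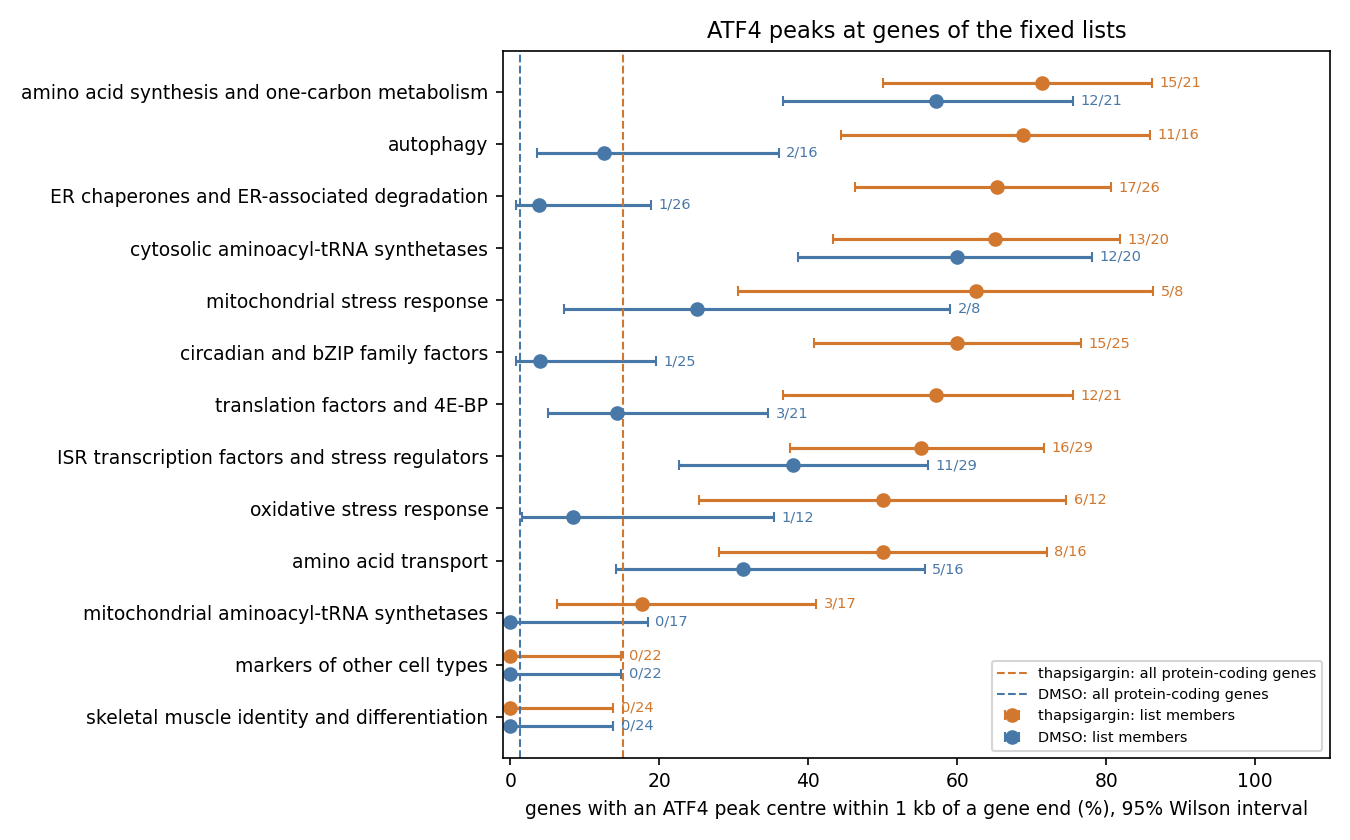
Share of the members of each fixed gene list (%) with an ATF4 peak centred within 1 kb of a gene end, in thapsigargin (orange) and DMSO (blue), with 95% Wilson intervals and counts; dashed lines are the shares over all protein-coding genes, 15.1% and 1.29%. The ER chaperone list stands at 17 of 26 in thapsigargin and 1 of 26 in DMSO, and the cytosolic synthetases at 13 of 20 and 12 of 20.

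In DMSO, 7 of the lists passed against a share of 1.29% of all genes. The synthesis list had 12 of 21 (odds ratio 105, adjusted exact p = 5.52e-17), the cytosolic synthetases 12 of 20 (odds ratio 118, adjusted exact p = 4.79e-17), the stress response regulators 11 of 29 (odds ratio 49.6, adjusted exact p = 3.17e-13) and the transporters 5 of 16 (odds ratio 37.3, adjusted exact p = 3.8e-06). Smaller counts passed for the translation factors (3 of 21, adjusted exact p = 0.00471), mitochondrial stress (2 of 8, adjusted exact p = 0.00759) and autophagy (2 of 16, adjusted exact p = 0.0268). The ER chaperone list had 1 of 26 (adjusted exact p = 0.371), oxidative stress 1 of 12 (adjusted exact p = 0.208), the circadian and bZIP factors 1 of 25 (adjusted exact p = 0.371) and the mitochondrial synthetases 0 of 17 (adjusted exact p = 1). The calls for autophagy and mitochondrial stress rest on 2 genes each and were lost under 4 and 2 other settings. The ER chaperone list passed with a window of 5 kb (3 of 26, adjusted exact p = 0.0248) or the nearest gene within 50 kb (4 of 26, adjusted exact p = 0.00967). The circadian and bZIP list also passed with the nearest gene (4 of 25, adjusted exact p = 0.00892).

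A last comparison, chosen after the list counts had been seen, asked which lists were already bound in DMSO among genes bound in thapsigargin, of which 8.39% had a DMSO peak too. The counts are per gene, not per site: at Sars and Gadd45a the nearest DMSO and thapsigargin peaks lay at opposite gene ends. Both of these DMSO peaks nonetheless overlapped another thapsigargin peak, so they mark no site of DMSO alone. The cytosolic synthetases were bound in DMSO at 12 of 13 thapsigargin-bound members (92.3%, adjusted exact p = 1.28e-11, two-sided Fisher's exact tests adjusted over 11 lists). Qars, named after its values were seen, was the exception. The amino acid synthesis genes were bound at 12 of 15 (adjusted exact p = 1.92e-10), the stress response regulators at 11 of 16 (68.8%, adjusted exact p = 1.31e-08) and the transporters at 5 of 8 (62.5%, adjusted exact p = 0.000499). The ER chaperone list was bound in DMSO at 1 of 17 (5.88%, adjusted exact p = 1), which was Xbp1, also named after its values were seen, and the circadian and bZIP factors at 1 of 15 (6.67%, adjusted exact p = 1). In the ER chaperone list Atf6, likewise named afterwards, did not count as bound in DMSO. Its DMSO peak lay inside its thapsigargin peak but was centred 1510 bp from the gene end. Autophagy had 2 of 11 (adjusted exact p = 0.368), the translation factors 3 of 12 (adjusted exact p = 0.133), oxidative stress 1 of 6 (adjusted exact p = 0.562), mitochondrial stress 2 of 5 (adjusted exact p = 0.13) and the mitochondrial synthetases 0 of 3 (adjusted exact p = 1).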

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

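The upper part of each list by width, the peak-edge distance, the centre match for rank and the test of lists already bound in DMSO were chosen after the data had been seen. No paired analysis was possible because each condition has a single list, taken to stand for both replicates, which also rules out leaving out a replicate. Of 327 alternative values, 278 kept direction and call, stayed within the interval or, for counts, differed from the main count by at most 1.5 times. These include lists with 0 members bound in DMSO, whose corrected odds ratios crossed 1 without a call. Mitochondrial synthetases went from 2.19 to 0.972 and markers of other cell types from 1.70 to 0.755 with the nearest gene, and muscle identity from 1.56 to 0.983 at 5 kb. The overlap of 99.5% of DMSO and 9.25% of thapsigargin peaks was 51.1% and 4.76% with centres within 100 bp, 25.5% and 25.3% against the 803 widest thapsigargin peaks, and 96.3% of DMSO peaks in the upper part by width, settings that allow fewer matches by construction. The share at a gene end moved with the window: in DMSO 22.4% at 500 bp, 37.2% at 3 kb and 33.4% with all gene types, in thapsigargin 26.5%, 38.4% and 36.8%. The odds ratio of shared peaks for a gene end passed the test at 500 bp (0.734) and with all gene types (0.842). It was 1.03 in the upper part by width, where peaks over narrower DMSO peaks counted as thapsigargin alone. The cause of these changes was not tested. The odds ratio of the mitochondrial synthetases in thapsigargin, 1.36 and not past the threshold, turned to 0.637 at 500 bp, 0.754 with the nearest gene and 0.774 against genes near a peak, on 3 genes or fewer; the cause was not tested. Of the other list odds ratios 141 kept their call, 9 lost it (autophagy and mitochondrial stress in DMSO, transport, oxidative and mitochondrial stress in thapsigargin) and 3 gained it (ER chaperones and bZIP factors in DMSO), and 5 to 8 lists passed in DMSO and 9 to 10 in thapsigargin. Size moved more than calls: of 102 alternative odds ratios of the lists that passed, 35 differed from the main one by over 1.5 times. In thapsigargin amino acid synthesis went from 13.5 to 6.42 at 500 bp, cytosolic synthetases from 10.2 to 5.64 and ER chaperones from 10.4 to 4.22 with the nearest gene, and stress regulators from 6.9 to 3.66 and autophagy from 11.8 to 5.95 against genes near a peak. In DMSO synthesis went from 105 to 45.6 and cytosolic synthetases from 118 to 51.0 with the nearest gene. Others rose: in thapsigargin cytosolic synthetases to 18.1 in the upper part by width and stress regulators to 11.3 with the nearest gene. In the upper part by width in DMSO, stress regulators went from 49.6 to 76.8 and transport from 37.3 to 66.0. The odds ratio of overlap at gene ends, 374, was 62.3 at 500 bp and 239 at 5 kb. Among the list members named by width, Ddit4, Stc2, Jdp2, Psat1, Shmt2, Phgdh, Slc6a9, Slc38a7, Vars, Eif4a1, Eif1, Ern1, Atf6, Wipi2, Gclm, Lonp1, Per2 and Junb had no thapsigargin peak centred within 500 bp of a gene end. A wide peak centred further away can still cover the gene end, as at Ddit4, Ern1 and Junb. The lists already bound in DMSO numbered 4 under each alternative but the peak-edge distance, which gave 5. Motif searches and a stricter q threshold were not run. Depth, unknown here, limits any reading of peak number and width.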

Other observations

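The gene families, gene types, runs of peaks, chromosome counts and the comparison of synthetase lists described here were chosen after the peak lists had been examined. So were the two-sided tests of the lists without peaks, which had already been seen to hold 0. The same goes for the tests of gene number on the X chromosome, of line order, and of width and of housekeeping genes over all lists. Among 22 gene families picked by symbol, 13 differed from other protein-coding genes in the share with a thapsigargin ATF4 peak at a gene end (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted), 8 of them above and 5 below. One family joined the translocon, the signal recognition particle and its receptor, signal peptidase and oligosaccharyltransferase, which act on proteins entering the ER. It had 14 of 30 genes with a peak (46.7%, adjusted exact p = 0.000302), among them Ostc, Spcs3, Srpr and Sec11a. The Kruppel-like factors had 8 of 17 (47.1%, adjusted exact p = 0.00498), with Klf13, Klf16, Klf6 and Klf11. Genes whose symbol begins with Rab and a digit had 22 of 69 (31.9%, adjusted exact p = 0.00223). These are the Rab GTPases of vesicle traffic and any other genes so named. COPII, COPI and p24 cargo genes had 11 of 34 (32.4%, adjusted exact p = 0.0236), with Sec23a and Sec16a, and the Hsp40 family 13 of 45 (28.9%, adjusted exact p = 0.0321). Housekeeping families also passed, with 14 of 37 genes of complex I (37.8%, adjusted exact p = 0.00223), 23 of 75 of the mitochondrial ribosome (30.7%, adjusted exact p = 0.00223) and 23 of 84 ribosomal protein genes (27.4%, adjusted exact p = 0.00735), while the proteasome did not (10 of 39, 25.6%, adjusted exact p = 0.115). The shares of the Rab, cargo and Hsp40 genes lay within the range of these housekeeping families. The collagen genes had no peak at a gene end (0 of 44, adjusted exact p = 0.00367), and the olfactory receptors had 3 of 1110 (0.27%, adjusted exact p = 3.32e-74).

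Of 408 tRNA genes, 63 (15.4%, interval 12.3% to 19.3%) had a thapsigargin peak within 1 kb, from 41 distinct peaks, where 20 shuffles of the peaks gave 2.8 genes and 2.25 distinct peaks on average and 5 at most of each. The share is close to the 15.1% of protein-coding genes, although the ends of those lie further apart and so take in more sequence. It is above the 5.41% of lncRNA, 3.09% of snRNA, 2.85% of miRNA and 1.57% of snoRNA genes and the 0.538% of pseudogenes. An excess over shuffles was also seen at lncRNA genes (687 against 168.45 on average), so it is not confined to tRNA genes. Of the 63 tRNA genes with a peak, 37, at 21 distinct peaks, lay over 1 kb from any protein-coding gene end, and 1 tRNA gene had a DMSO peak. Shuffles spread peaks over the whole annotated chromosome, and tRNA genes lie in clusters, so the count of distinct peaks is the safer one. Thapsigargin peaks also came in runs, with 569 runs of at least 2 peaks at most 10 kb apart. Over 100 random placements within chromosomes there were 319.1 runs on average and 357 at most, and 383.4 and 423 when the peaks at gene ends were placed at random gene ends. The longest run, of a length that random gene ends also reached, held 6 peaks over 38.2 kb around Etf1 and Hspa9, the gene of mitochondrial Hsp70 (chromosome 18, 34931442 to 34969595), and 3 of the 6 were also in DMSO. A run of 5 peaks on chromosome 8, from 126832072 to 126853138, overlapped no protein-coding gene and none of its peaks was in DMSO.

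The cytosolic synthetase genes had a thapsigargin peak more often than the mitochondrial ones (13 of 20 against 3 of 17, two-sided Fisher's exact test, p = 0.00707). The muscle identity list had 0 of 24 where 3.62 would match all genes at 1 kb (two-sided Fisher's exact test, p = 0.0402, not adjusted), and the markers of other cell types 0 of 22 where 3.32 would match (p = 0.0652). The odds ratio of the muscle list was 0.143 at 500 bp, 0.105 by peak edge and 0.0927 against genes with a peak within 50 kb, but 0.416 at 5 kb and 0.881 with the nearest gene within 50 kb.

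The first pattern weighed is that 10 of 13 lists carried thapsigargin peaks more often than other genes. Open promoters of active genes attract the transposase, so transcribed genes in general could give this. Housekeeping families (ribosomal proteins, proteasome, mitochondrial ribosome, complex I and mitochondrial synthetases) had a peak at 29.0% of 252 genes (interval 23.7% to 34.9%), above the 15.1% of all genes. The lists that passed had 61.1% of 193, but they were chosen by that share; the members of all 13 lists had 47.3% of 256 (interval 41.2% to 53.4%), against 29.8% of the 235 housekeeping genes outside the lists (interval 24.3% to 35.9%). This argues against open promoters of the kind that housekeeping genes have as the whole cause. They remain a candidate explanation of part of the excess over all genes. The comparison cannot weigh promoters that are more open at stress genes than at housekeeping genes, as no accessibility or expression values were used here. Binding of ATF4 through its own sites was not tested without sequence.

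The second pattern is that, within 1 kb of gene ends, stress regulator, amino acid synthesis, transport and cytosolic synthetase genes had peaks in both conditions, while ER chaperone, autophagy and bZIP genes had them mostly in thapsigargin. Of the thapsigargin-bound genes, 40 of 52 in the first set and 4 of 43 in the second had a DMSO peak, a difference of 67.6 percentage points, but these sets were chosen by that share, so random draws are no fair match for it. Over all 11 lists with thapsigargin-bound members, with no choice among them, the chi-square of the DMSO-bound share was 53.2, against a mean of 10.3 and at most 42.1 in 10000 draws of genes matched on thapsigargin peak width (one-sided permutation p = 1e-04, the smallest they can give), which argues against width as the whole cause. Some ER genes had DMSO peaks beyond 1 kb or in another list (Hspa5 at 1843.5 bp, Atf6 at 1510 bp and the regulator Herpud1 at 24 bp, picked after their values were seen), and at 5 kb 3 of 19 thapsigargin-bound chaperone genes had one (adjusted exact p = 0.65), against 14 of 20 regulators (adjusted exact p = 5.79e-10). Width is a loose stand-in for signal, so a difference in peak height between the lists stays open, and no biological explanation was tested.

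The third pattern is the X chromosome, which had 114 thapsigargin peaks (0.668 per Mb of annotated span, against 2.51 to 5.25 on the autosomes) and 6 DMSO peaks. Fewer genes there do not account for it, since 45 of 966 X-linked protein-coding genes (4.66%) had a peak against 15.6% of autosomal ones (odds ratio 0.265, interval 0.191 to 0.358). X peaks were narrower, by a median width percentile that differed by -9.35 (bootstrap interval -17 to -2.37). A weaker signal from fewer copies per cell would give this, but the number of X copies in these cells is not known here. Other causes of weak signal, such as less open chromatin, would give the same. The share of X peaks also in DMSO was 5.26%, against 9.3% on the autosomes (two-sided Fisher's exact test, p = 0.19). Peak width does not tell copy number from other causes of weak signal, and no further biological explanation was tested.

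A hypothesis that new peaks gather around sites bound in DMSO was not borne out either way: 589 of 7822 thapsigargin-only peaks had a shared peak within 50 kb, against 563.9 on average over random relabellings within a chromosome (one-sided permutation p = 0.14). The DMSO list was not in genome order, and peak width rose along its lines (Spearman's rho across peaks 0.447, bootstrap interval 0.39 to 0.502, permutation p = 1e-05, the smallest they can give). The DMSO peaks at genes of the 10 lists that passed in thapsigargin stood late in it (median line 677, against 388 for the others, permutation p = 1e-05). This was not tested apart from width, which is not a measure of occupancy. The list does not state its order, and whether it follows peak strength cannot be told from these values.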
